A study of Homo sapiens with 18 samples.

How the data were processed

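Total RNA of 18 samples of 6 breast cancer cell lines was extracted with Trizol, labelled with biotin through a whole-transcript sense target kit and hybridised to expression arrays, per the labels' protocols. The submitters' processing notes name Affymetrix Power Tools and the genome build hg19, with no version, role or order. The deposited table holds 33297 rows and 18 columns, 1 per sample and none of any other sample, and its values are on the log2 scale as deposited. The summarisation, the background correction and the normalization that made these values are not stated in the labels. Detection calls and scanner files were not used here, so signal over background is unknown, and control rows could not be told from other rows.

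Rows were named through the platform annotation paired with the table. Of the rows, 19460 carry 1 gene symbol, 1754 carry several and 12083 carry none. Of the rows with 1 symbol, 19429 matched the RefSeq gene table of GRCh38.p14 by Entrez identifier, which changed 0 symbols. That table served only for names, chromosomes and the order of neighbouring genes, and no coordinates are given because the submitters' build is another. Rows with several symbols or none were left out of the gene tests, as were 24 rows of XIST, TSIX and chromosome Y genes. Where a gene had several rows (768 genes) the row with the highest mean over the 18 samples was kept, which left 18394 genes.

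The acetylation level is a property of the cell line. The main test between levels was therefore fitted with limma 3.58.1 in R 4.3.3 on the 6 line means, 3 Acetyl against 3 Hypo, with empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes, at an adjusted p of 0.05. Genes that separate the levels are those with an adjusted p under 0.05 and the same direction in all 9 pairs of an Acetyl and a Hypo line, in a limma fit of all 18 samples with a coefficient per line. The same fit gave each line against the mean of the other 5 and MCF7 against the mean of the 3 Acetyl lines, at an adjusted p of 0.05 and a log2 difference of at least 1. All p-values are two-sided. In these fits the error is the spread between the samples of a line, and the labels do not say whether those samples are separate cultures. Variance shares are nested sums of squares of level, line within level and sample, with no test.

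Before the data were examined, 21 gene lists were fixed: histone acetyltransferases and coactivators, deacetylases and sirtuins, acetyl-lysine readers, acetyl-CoA supply, histone and DNA methylation writers and erasers, genes known to rise with deacetylase inhibitors, oestrogen receptor and luminal, basal epithelial, ERBB2 amplicon, androgen receptor and apocrine, mesenchymal transition, epithelial junction, cell cycle, interferon response, MHC class I presentation, sterol synthesis, glycolysis and hypoxia, cancer-testis, replication-dependent histone genes, and markers of fibroblasts and of blood and endothelium. Lists were tested with camera at a preset correlation of 0.01, on the line means for the level and on the 18 samples for each line, and again with an estimated correlation. Adjustment was over the 21 lists for the level and over the 126 pairs of list and line for the lines. Members were counted over all genes and adjusted over the list alone. Members whose rows carry several symbols, such as the classical HLA genes and AR, were not measured.

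The genes named in the text follow a rule set together with the lists. For the level these are the 15 genes with the largest difference in each direction among those called, filled from the separating genes where fewer were called. Since 0 genes were called, all 30 come from the separating genes and are given as values. For each line the rule takes the 5 highest and 3 lowest genes, for MCF7 against the Acetyl lines the 8 highest and 8 lowest, for each list the 4 members with the largest difference, and always ESR1, PGR, GATA3, FOXA1, ERBB2, EGFR, KRT5, VIM and CDH1. Members named because they passed over their list alone, or because they are the only member that separates the levels, fall under the counts they belong to. The 4 members of a list were taken by the size of the difference, whether or not they separate the levels.

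Alternatives fixed at the same time were quantile normalization, centring each array on its median, leaving out the 40% of genes with the lowest mean, the mean of a gene's rows, every row of the table, an intensity trend with robust moderation, the line as a random block (duplicateCorrelation, consensus correlation 0.862), samples as if independent, line coefficients with the error within lines, the replicate number as a block, other thresholds, and leaving out each line and each sample. The row alternative could not leave out control rows. For the 6 lines, all 10 splits into 3 and 3 were compared, and for the line contrasts 100 regroupings of the samples, the real grouping included.

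The tests were checked on simulated data drawn from the means and spreads of the 18394 genes, with 200 genes changed in each of 5 draws. For Acetyl against Hypo on line means, 30.1% of genes changed by 1 on the log2 scale were recovered, 59.4% of those changed by 2 and 82.1% of those changed by 4, with a mean of 8.6 false calls per draw. The changed genes were drawn at random from all genes, whatever their spread between lines. These shares are therefore not the power for genes that vary much between lines. In the same draws a mean of 443.2 unchanged genes met the rule for separating genes. For a line against the other 5, drawn with no other difference between lines, all genes changed by 1, 2 or 4 were called (100.0%), with a mean of 10.6 false calls per draw before the minimum difference. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.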

Results

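RNA of 6 established human breast cancer cell lines was measured on 18 whole-transcript expression arrays, with 3 samples of each line. The labels give each line an acetylation level. BT474, MdaMB361 and T47D are labelled Acetyl, and BT20, MCF7 and SkBr3 are labelled Hypo. The study's title and design state that expression was profiled in lines that differ in acetylation level, and the labels do not say which acetylation was measured or how. The level belongs to the line and not to the sample, so each level holds 3 lines and 9 samples. Array medians lay between 6.73 and 6.81 on the log2 scale. The lowest deposited value was 2.06, and 18394 named genes were tested. The number of lines limits the precision of every comparison between the levels.

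The marker genes gave each line a clear and separate profile. ESR1, the oestrogen receptor, was at 9.24 in BT474, 10.12 in MdaMB361, 10.32 in T47D and 10.16 in MCF7, against 6.89 in BT20 and 5.90 in SkBr3 (log2 means of 3 samples each). GREB1, an oestrogen-responsive gene, followed the same division, with 11.27 in MCF7, 5.48 in BT20 and 6.19 in SkBr3. ERBB2, the receptor tyrosine kinase HER2, was at 12.81 in BT474, 12.77 in SkBr3 and 11.68 in MdaMB361, against 8.81 in MCF7. EGFR, a related receptor, was at 12.27 in BT20 and 10.37 in SkBr3 and at or below 7.71 in the other lines. KRT5, a keratin of basal epithelium, was at 12.84 in BT20 and at or below 7.09 elsewhere. CDH1, the epithelial adhesion protein E-cadherin, was at 5.81 in SkBr3 and at or above 12.13 elsewhere. GATA3 and FOXA1, transcription factors of luminal epithelium, were lowest in SkBr3 at 9.53 and in BT20 at 10.24. VIM, an intermediate filament of mesenchymal cells, was at 9.37 in BT474 and at or below 6.49 elsewhere. The largest standard deviation among the 3 samples of a line was 0.37 for these 9 genes, in CDH1.

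**Figure D1:**
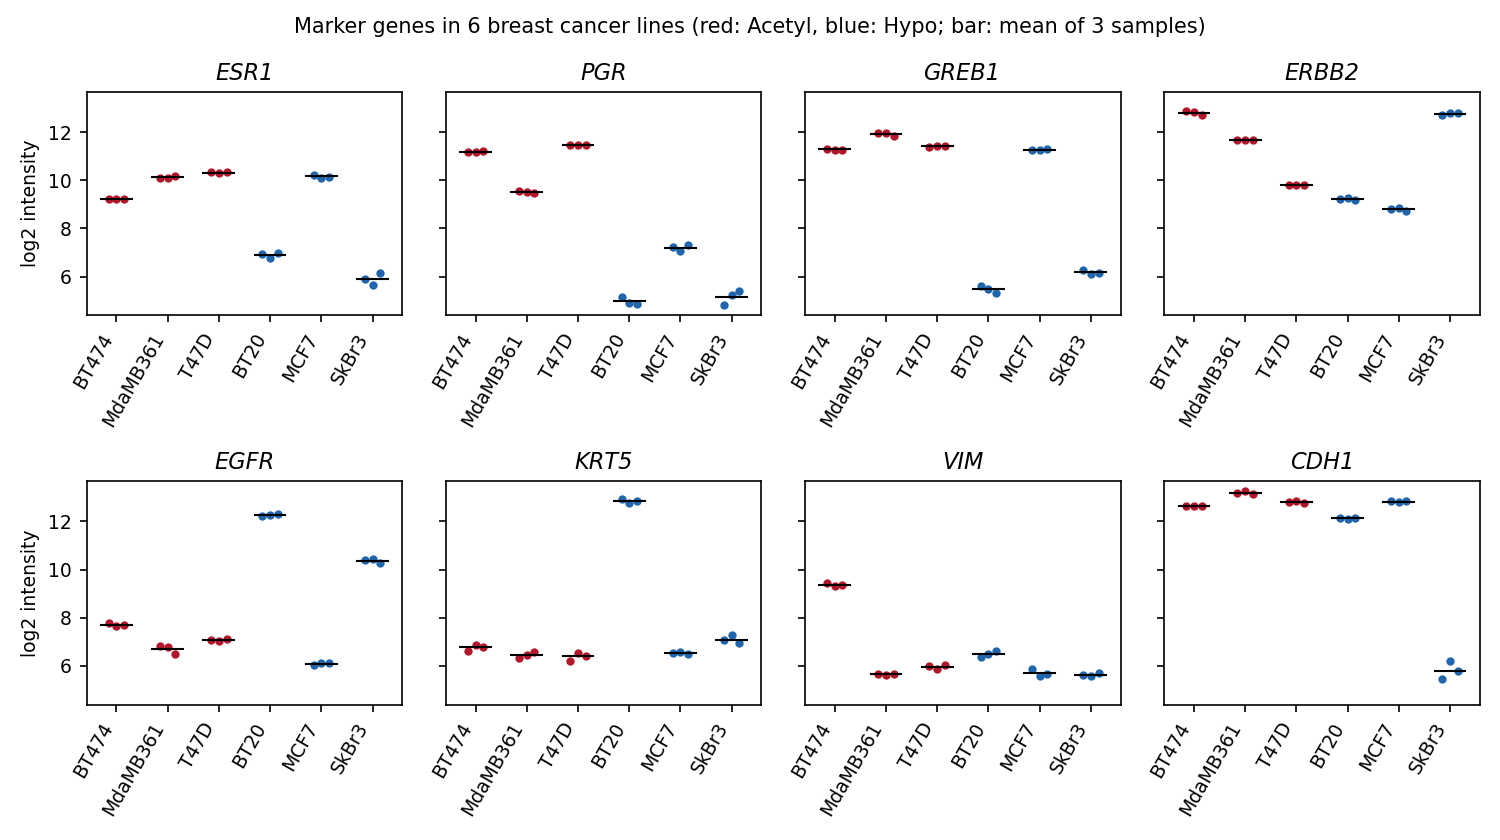
Log2 intensity of 8 marker genes (vertical axes) in the 18 samples, grouped by cell line (horizontal axes), with red points for the Acetyl lines, blue points for the Hypo lines and a bar at the mean of 3 samples. ESR1 and GREB1 are high in MCF7 and in the 3 Acetyl lines, and the line mean of PGR is 9.52 in MdaMB361, higher in the other 2 Acetyl lines and lower in the 3 Hypo lines.

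The first comparison asked which genes differ between the lines labelled Acetyl and those labelled Hypo. The most prominent genes higher in all 3 Acetyl lines were copies of SNORD116, small nucleolar RNAs of an imprinted cluster on chromosome 15. SNORD116-14 had a mean of 11.66 ± 0.39 in the Acetyl lines and 4.97 ± 1.64 in the Hypo lines (SD of 3 line means), a log2 difference of 6.69 with an SE of 0.84. SNORD116-24, SNORD116-20, SNORD116-1 and SNORD116-15 differed by 6.24, 6.19, 5.93 and 5.84, and SNORD116-21 and SNORD116-6 by 4.33 and 4.06. The copies are related in sequence, so the share of each copy is uncertain and they count here as a single locus. Their levels differed widely within a line, from 3.44 for copy 16 to 12.96 for copy 15 in BT474. With cell line as the replicate, no gene passed an adjusted p of 0.05 in limma, in either direction. At an unadjusted p under 0.05 there were 671 higher and 623 lower genes in the Acetyl lines, and the adjusted p of SNORD116-14 was 0.266. At an adjusted p of 0.1 there were 6 genes, all higher in the Acetyl lines, with SNORD116-1 at 0.0799 and SNORD116-6 at 0.0822.

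**Figure D2:**
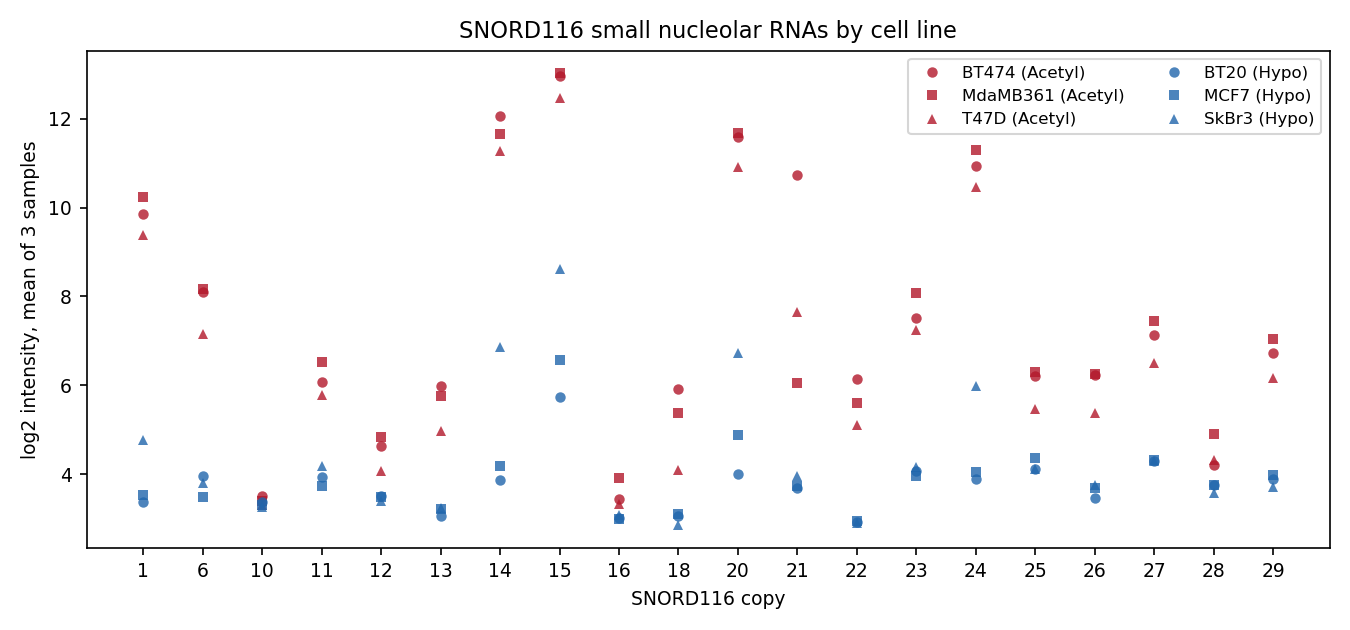
Log2 intensity (vertical axis, mean of 3 samples) of the 20 measured SNORD116 copies (horizontal axis) in each cell line, with red symbols for Acetyl lines and blue symbols for Hypo lines. In 18 of the 20 copies every Acetyl line lies above every Hypo line by a difference past the threshold in all 9 line pairs. SkBr3 lies well above the other Hypo lines for copies 1, 14, 15, 20 and 24, and above them by less for copies 11, 13, 16, 21, 23 and 26.

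The genes named here for the level are those that separated the levels in all 9 pairs of an Acetyl and a Hypo line, each pair at an adjusted p under 0.05 in limma with the spread between samples of a line as the error. There were 362 such genes higher and 319 lower in the Acetyl lines, which describes these 6 lines and does not extend to other lines. PGR, the progesterone receptor, had 10.72 ± 1.06 in the Acetyl and 5.78 ± 1.23 in the Hypo lines, with 7.20 in MCF7. LRRN1, a leucine-rich repeat membrane protein, differed by 4.53 and NCAM2, a neural cell adhesion molecule, by 4.17. SLC40A1, the iron exporter ferroportin, had 11.21 ± 0.81 against 6.78 ± 2.83, with SkBr3 at 10.05 close to the Acetyl lines. HEY2, a Notch target, differed by 4.21, FADS2, a fatty acid desaturase, by 4.18, ANKRD30B by 3.99 and the sialyltransferase ST6GALNAC2 by 3.99. FADS2 was between 9.27 and 9.365 in the MCF7 samples, close to T47D at 9.49 to 9.66. None of these genes passed the test on line means, and their adjusted p there ran from 0.389 for PGR and LRRN1 to 0.647 for SLC40A1.

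Among the genes that were lower in the Acetyl lines in all 9 pairs, CASP14, a caspase of epidermal differentiation, had 5.33 ± 0.46 in the Acetyl and 9.48 ± 1.39 in the Hypo lines. MAP7D3, a microtubule-associated protein, and TSPYL5 had 4.97 and 4.98 in the Acetyl lines and 9.02 and 9.01 in the Hypo lines. CAV1, a structural protein of caveolae, had 6.02 ± 0.56 against 10.03 ± 2.50, and LPCAT2, a lysophospholipid acyltransferase, 6.49 ± 1.22 against 10.37 ± 1.42. The immediate early transcription factors FOS, FOSB and EGR1 had differences of -3.48, -2.99 and -2.95. The matrix cross-linking enzyme LOXL2 had a difference of -2.91, the integrin subunit ITGB6 -2.91, tissue factor F3 -2.75, the deiodinase DIO2 -2.74 and the mitochondrial carrier SLC25A43 -2.71. The differences of F3 and DIO2 came mainly from BT20 and SkBr3. In the MCF7 samples F3 was between 7.01 and 7.24 and DIO2 between 4.94 and 5.36, close to the highest Acetyl samples at 6.88 and 4.84. PLAC8 had a difference of -3.14. ME1, malic enzyme, had -3.12, which came mainly from T47D, where it was at 3.97 against 9.54 or more in every other line. The adjusted p on line means was 0.389 or higher for all of these, and 0.803 for ME1.

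**Figure D3:**
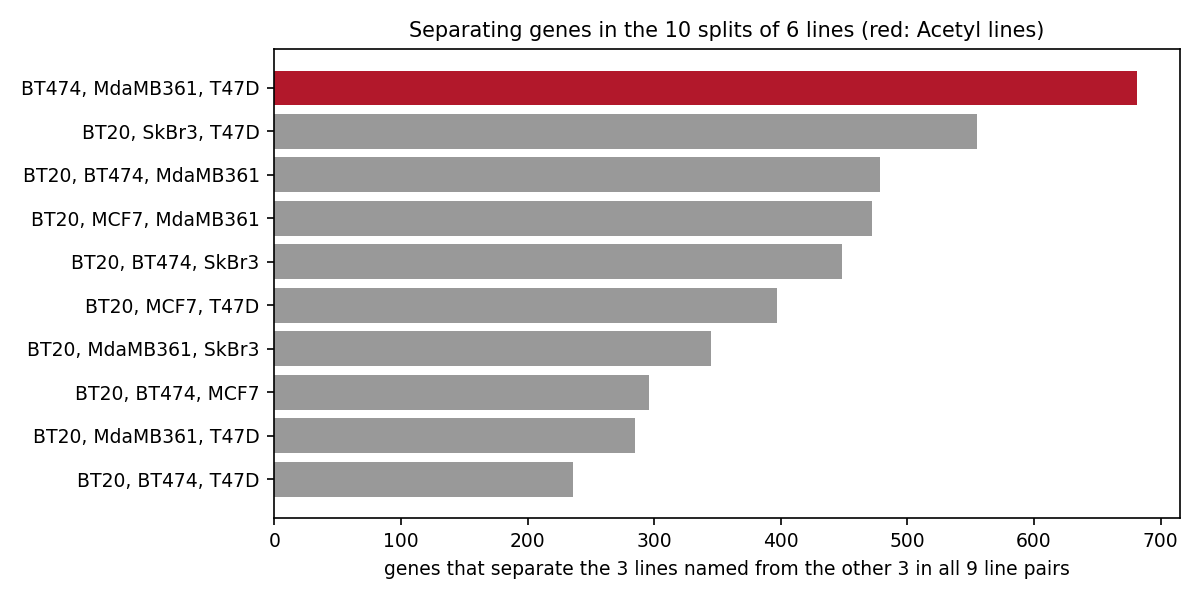
Number of genes (horizontal axis) that separate the 3 named lines from the other 3 in all 9 line pairs, for each of the 10 splits of the 6 lines (vertical axis), with the split by acetylation level in red. The split by level has 681 such genes and the other splits have 236 to 555.

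The count of genes called between the levels depended on what was taken as the replicate. With all 18 samples and the line as a random block, 378 genes were higher and 303 lower, and with the samples as if independent 1653 were higher and 1622 lower. Leaving out T47D gave 9 higher and 3 lower genes on line means, leaving out SkBr3 gave 7 and 3, and leaving out MCF7 gave 2 and 4.

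Gene lists were compared between the levels with camera on the 6 line means. Genes of the oestrogen receptor and luminal programme were higher in the Acetyl lines, with 28 of 29 measured members above 0, a median log2 difference of 1.09 and an adjusted p of 1.3e-06. With an estimated correlation among the members the adjusted p was 0.455. PGR and NAT1, a luminal acetyltransferase of arylamines, passed when adjusted over the list alone, each with an adjusted p of 0.0179, and 0 members passed over all genes. TFF3, GREB1 and IGFBP4 differed by 2.92, 3.90 and 2.87, with GREB1 in MCF7 at the level of the Acetyl lines. Androgen receptor and apocrine genes were higher in the Acetyl lines, with 11 of 13 members above 0, a median of 1.52 and an adjusted p of 0.0193, or an adjusted p of 0.455 with an estimated correlation. Of these, PRLR, the prolactin receptor, differed by 3.23, ALOX15B, a lipoxygenase, by 2.28, and the secreted proteins PIP and AZGP1 by 2.27 and 2.13, both of which were high in T47D alone among the 6 lines, at 12.47 and 12.55.

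Lists of the acetylation machinery had small medians, with single members that differed more. Histone acetyltransferases and coactivators were higher in the Acetyl lines, with 17 of 25 members above 0, a median of 0.26 and an adjusted p of 0.0193, or an adjusted p of 0.455 with an estimated correlation. KAT7 (HBO1) had 11.12 ± 0.61 in the Acetyl and 9.53 ± 0.64 in the Hypo lines, KAT6A (MOZ) 10.18 ± 0.48 and 8.96 ± 0.15, and these are 2 of the 4 members that separated the levels in all 9 pairs. TADA2A and KAT2B (PCAF) differed by 1.00 and -0.99 without separating the levels. Deacetylases and sirtuins did not pass, with an adjusted p of 0.587, and their median of -0.03 and mean of 0.08 differed in sign. HDAC6, a cytoplasmic deacetylase that acts on tubulin, was the only one of 18 members that separated the levels, with 8.68 ± 0.33 in the Acetyl and 7.65 ± 0.33 in the Hypo lines. HDAC11, SIRT4 and HDAC8 differed by 0.51, 0.40 and -0.32. Readers of acetyl-lysine had an adjusted p of 0.587, with a median of 0.09 and a mean of -0.0062, and TRIM33 separated the levels with a difference of -1.16. BAZ2B and KAT2A differed by 0.88 and -0.86.

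Genes of acetyl-CoA supply had an adjusted p of 0.247. CRAT, carnitine acetyltransferase, differed by 2.83, PDK2, a pyruvate dehydrogenase kinase, by 1.45, and ACACB, an acetyl-CoA carboxylase, by -1.68 with 9.65 in MCF7 as its highest line mean. ACSS3 differed by -1.38. Writers and erasers of histone and DNA methylation were higher in the Acetyl lines, with 25 of 39 members above 0, a median of 0.20 and an adjusted p of 0.0311, or an adjusted p of 0.455 with an estimated correlation. NSD3, SUZ12 and KDM5C differed by 0.84, 0.77 and 0.73, and KDM4C by -0.94. Genes known to rise with deacetylase inhibitors did not pass as a list, with an adjusted p of 0.309. GSN, the actin-severing protein gelsolin, and MT1X, a metallothionein, differed by 1.39 and -2.36, each with an adjusted p of 0.0303 when adjusted over the list alone. TNFSF10 (TRAIL) and TGFBR2 differed by 3.64 and -2.08. Replication-dependent histone genes had a median of -0.0048 over 58 members and an adjusted p of 0.905, with H4C4, H1-1, H3C8 and H2AC11 at 2.50, -1.92, -1.49 and -1.48.

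Lists that were lower in the Acetyl lines were those of glycolysis and hypoxia and of mesenchymal transition. Of 27 glycolysis and hypoxia genes 21 were below 0, with a median of -0.25 and an adjusted p of 0.0193, or an adjusted p of 0.455 with an estimated correlation. LDHA, lactate dehydrogenase A, at -0.67 was the only member called when adjusted over the list alone, with an adjusted p of 0.0442. NDRG1, ALDOC and P4HA1 differed by -1.34, -1.20 and -1.08, and LDHB by 1.77. Of 19 mesenchymal transition genes 13 were below 0, with a median of -0.37 and an adjusted p of 0.0248, or an adjusted p of 0.455 with an estimated correlation. SNAI2, a transcriptional repressor of epithelial genes, differed by -3.57, FN1, fibronectin, by -3.36 and CCN1 by -2.13, and CDH2, N-cadherin, by 2.52. Of the 21 lists, 4 were higher and 2 lower in the Acetyl lines, and 0 passed with an estimated correlation, where the lowest unadjusted p was 0.0785. Leaving out BT474 gave 2 higher and 0 lower lists, and leaving out SkBr3 gave 5 lower lists.

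At the preset correlation the call of the oestrogen receptor and luminal list held whichever line was left out, with an adjusted p of at most 0.0021, while with an estimated correlation and all lines it did not pass, with 0.455. The other 5 calls at the preset correlation were each lost when any of 2 or 3 lines was left out. For histone acetyltransferases the adjusted p was 0.19 without SkBr3 and 0.0538 without BT474. For methylation writers and erasers it was 0.269 without SkBr3, 0.126 without BT474 and 0.0998 without MdaMB361, and with all lines it was 0.0596 without the 40% lowest genes. For the apocrine list it was 0.127 without BT20 and 0.0544 without MCF7. For mesenchymal transition it was 0.209 without T47D, 0.0632 without BT20 and 0.0538 without BT474, and for glycolysis and hypoxia 0.11 without T47D and 0.0706 without BT474.

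The remaining 15 lists did not pass with all 6 line means as deposited, and 8 of them passed under some alternative at the preset correlation, as given after their values. The adjusted p was 0.0587 for basal epithelial genes, whose median was -0.72 with CAV1, EGFR, KRT5 and MET at -4.01, -2.41, -2.29 and -1.81. It was 0.0587 for genes of the ERBB2 amplicon, whose median was 0.58 with PGAP3, STARD3, ERBB2 and MIEN1 at 1.42, 1.28, 1.16 and 1.08. MHC class I presentation genes had an adjusted p of 0.0661, with TAP2 at -1.08, PSMB10 at -0.86, PSMB9 at -0.76 and B2M at -0.73. Interferon response genes had an adjusted p of 0.127, and the antiviral membrane proteins IFITM3, IFITM2 and IFITM1 differed by -2.01, -1.95 and -1.89 while MX2 differed by 2.34. Sterol synthesis genes had an adjusted p of 0.172, with TM7SF2, HMGCS1, SREBF2 and STARD4 at 1.62, 0.84, 0.58 and 0.51. Cell cycle genes had an adjusted p of 0.587, with the cyclins CCNE1 and CCNE2 at -1.09 and 1.05 and KIF11 and MCM3 at 0.64 and 0.59. Epithelial junction genes had an adjusted p of 0.196, with CDH1 at 2.62, CLDN3 at 0.98, CLDN1 at -1.58 and TJP3 at 0.87. Cancer-testis genes had an adjusted p of 0.192, with SAGE1, DDX43 and MAGEC1 at -0.71, -0.56 and -0.47 and MAGEA8 at 0.41. Markers of other cell types gave an adjusted p of 0.815 for fibroblasts and 0.587 for blood and endothelium. For fibroblasts the median was 0.0035 and the mean -0.02, with ACTA2, S100A4, LUM and COL1A1 at -1.40, 0.51, 0.48 and 0.34. For blood and endothelium CDH5, LYZ, CD68 and CD14 were at -1.91, 0.75, -0.72 and -0.19.

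Basal epithelial genes passed as lower after quantile normalization (adjusted p 0.0439), with the line as a random block (0.00849), without MCF7 (0.00125) and without SkBr3 (0.0109). MHC class I presentation genes passed as lower without the 40% lowest genes (0.0387), with the random block (0.0188), without MCF7 (0.0317) and without T47D (0.00578). ERBB2 amplicon genes passed as higher with the random block (0.0110), without SkBr3 (3.3e-05), without T47D (0.00578) and without MdaMB361 (0.0270). Interferon response genes passed as lower without SkBr3 (0.0109) and without T47D (0.0274), cell cycle genes as lower without SkBr3 (0.00721), sterol synthesis genes as higher without MCF7 (0.00376) and acetyl-CoA supply as higher without MdaMB361 (0.0270). Replication-dependent histone genes passed as lower without MdaMB361 (0.0270) and as higher without MCF7 (0.0444). Leaving out another line took the other lists further from the threshold. The adjusted p was 0.792 for basal epithelial and 0.604 for sterol synthesis genes without BT20. Without BT474 it was 0.763 for the ERBB2 amplicon, 0.763 for interferon response, 0.501 for MHC class I presentation and 0.869 for cell cycle genes. Acetyl-CoA supply had 0.696 without T47D.

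**Figure D4:**
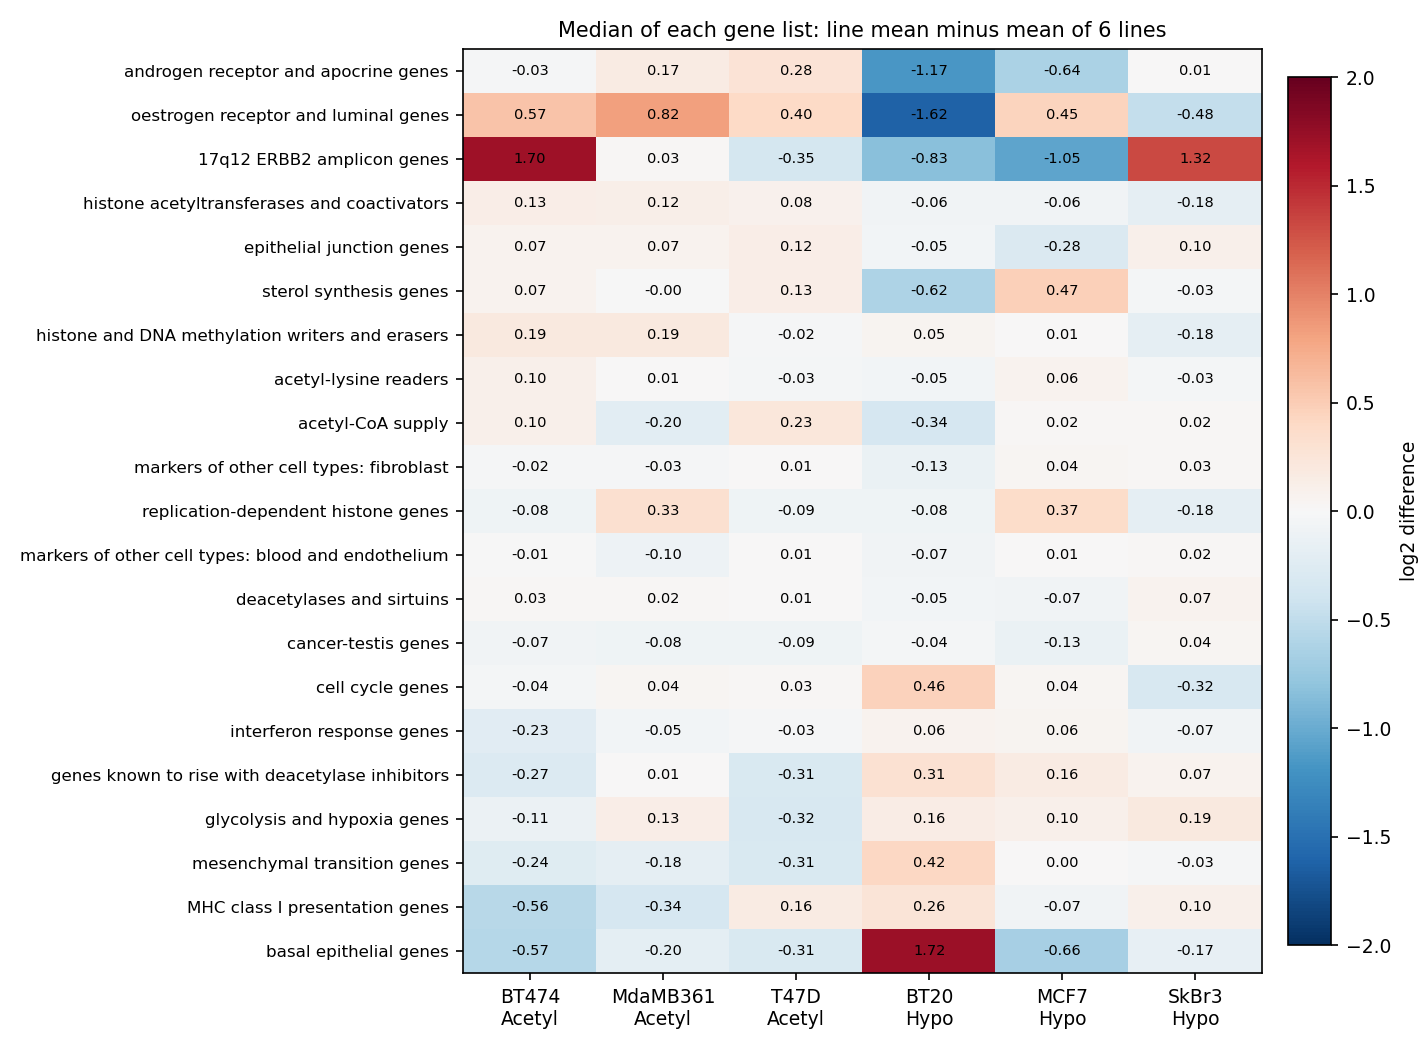
Median over the members of each of the 21 gene lists (rows) of the line mean minus the mean of the 6 lines, in log2 units, for each cell line (columns). BT20 holds the highest basal epithelial median at 1.72 and the lowest oestrogen receptor and luminal median at -1.62, and BT474 and SkBr3 hold the highest ERBB2 amplicon medians at 1.70 and 1.32.

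The next comparison set each line against the other 5, to describe what each line expresses. In BT20, 1211 genes were higher and 933 lower at an adjusted p under 0.05 in limma and a log2 difference of at least 1. The highest were TDRD12, a tudor domain protein, at 6.78 above the mean of the other 5 lines, the aldo-keto reductase AKR1B10 at 6.20, KRT5 at 6.19, POPDC3 at 5.95 and the kallikrein KLK6 at 5.86. The lowest were AGR2, a protein disulfide isomerase of secretory epithelium, at -7.23, PRLR at -5.77 and ALDH7A1 at -5.76. Of 20 basal epithelial genes 14 were higher and 0 lower, and of 29 oestrogen receptor and luminal genes 20 were lower and 1 higher. Both lists kept a call with an estimated correlation, with adjusted p of 0.00211 and 0.0114. So did the lower ERBB2 amplicon genes, with an adjusted p of 0.0139, and the lower androgen receptor and apocrine genes, with an adjusted p of 0.0228.

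In SkBr3, 766 genes were higher and 937 lower. GLYATL2 was 6.61 above the mean of the other 5 lines, CPS1, the first enzyme of the urea cycle, 6.25, GSDMB, a gasdermin encoded near ERBB2, 5.89, the lipoprotein receptor OLR1 5.59 and OLFM4, a secreted glycoprotein of intestinal stem cells, 5.48. OLFM4 was as high in BT20, at 12.01 against 11.72 in SkBr3. CDH1 at -6.91, the cytidine deaminase APOBEC3B at -6.51 and ZNF724 at -5.62 were the lowest. Of 18 ERBB2 amplicon genes 11 were higher and 0 lower, with an adjusted p of 0.0114 with an estimated correlation. In MCF7, 666 genes were higher and 692 lower. TFPI, a coagulation inhibitor, was 5.89 above the mean of the other 5 lines, followed by SYNPO2 at 5.47, LXN at 5.23, NECAB1 at 4.995 and TMTC1 at 4.88, while IGFBP5, which binds insulin-like growth factors, was at -6.59, CNN3 at -5.60 and TMBIM1 at -5.22. Of the ERBB2 amplicon genes 11 were lower in MCF7 and 0 higher, with an adjusted p of 0.00505 with an estimated correlation, and basal epithelial genes were lower with 0.0228. The mean of the other 5 lines includes BT20, where basal genes were high. Against the Acetyl lines alone the basal median in MCF7 was -0.13.

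Among the Acetyl lines, BT474 had 694 higher and 642 lower genes. TCN1, a cobalamin-binding protein, was 6.11 above the mean of the other 5 lines, SNORD116-21 5.70, the cystatin CST1 4.87, FAM3B 4.64 and the amino acid transporter SLC6A14 4.59, and TMCO1 at -6.20, CLDN1 at -4.78 and the histone gene H3C11 at -4.70 were the lowest. Of the 18 ERBB2 amplicon genes 14 were higher and 0 lower in BT474, with an adjusted p of 0.00277 with an estimated correlation, and the basal epithelial and interferon response lists were lower, each with an adjusted p of 0.0423. Here too BT20, where basal genes were high, is among the other 5 lines. MdaMB361 had 721 higher and 476 lower genes, with TCN1 at 6.13 by the same measure and as high as in BT474 (13.25 and 13.24), the mammaglobin SCGB2A2 at 5.75, TFAP2B at 5.34, FMOD at 4.83 and MUCL1, a small mucin-like protein of breast, at 4.81. TM4SF1 at -4.24, DNAJC15 at -3.97 and PTGES at -3.55 were the lowest. Of 29 oestrogen receptor and luminal genes 14 were higher and 0 lower in MdaMB361, with an adjusted p of 0.0142 with an estimated correlation. BT20 and SkBr3, where these genes were low, are among the other 5 lines. T47D had 817 higher and 668 lower genes. GNG11 was 7.71 above the mean of the other 5 lines, SERPINA6, which binds corticosteroids, 7.21, PIP 6.82, LRRN3 6.21 and PCDHB8 5.605, and ME1 at -6.54, TES at -5.99 and FZD6 at -5.60 were the lowest. The ERBB2 amplicon list was lower in T47D, with 4 members lower and 0 higher and an adjusted p of 0.0423 with an estimated correlation. BT474 and SkBr3, where amplicon genes were high, are among the other 5 lines for T47D, as they are for BT20 and MCF7. Relative to the mean of the 6 lines the amplicon median was -0.346 in T47D, above -0.835 in BT20 and -1.048 in MCF7.

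Over all 6 lines, 38 of 126 pairs of list and line passed an adjusted p of 0.05 in camera, 17 of them higher and 21 lower, and 12 passed with an estimated correlation, which are the 12 given above. Random regroupings of the 18 samples, which mix the lines, passed 14 to 38 pairs with a median of 25 at the preset correlation. The 3 samples of a line come from the same line, so these p-values describe differences between these lines and not between kinds of tumour.

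MCF7, the Hypo line with high ESR1, was then set against the 3 Acetyl lines, which all have high ESR1. In MCF7, 706 genes were higher and 815 lower. TFPI was higher by 6.04, SYNPO2 by 5.46, LXN by 5.18, NECAB1 by 4.91, TSPYL5 by 4.91, WIPF1 by 4.79, CASP14 by 4.74 and the metalloproteinase inhibitor TIMP3 by 4.68. SNORD116-14 differed by -7.47, SNORD116-24 by -6.84, IGFBP5 by -6.57, SNORD116-20 by -6.50, SNORD116-1 by -6.29, SNORD116-15 by -6.24, SLC40A1 by -6.12 and the epithelial transcription factor EHF by -5.62. The SE of these 16 differences ran between 0.05 and 0.16. ESR1 differed by 0.27 and GREB1 by -0.27, while PGR differed by -3.53. With the spread between the 3 Acetyl lines as the error, 0 genes passed an adjusted p of 0.05 in limma, against 796 higher and 584 lower at an unadjusted p under 0.05.

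The level took a median of 9.90% of a gene's sum of squares (quartiles 2.26% and 26.3%), the line within a level 62.5% (37.1% and 83.8%) and the samples of a line 7.83% (2.53% and 42.6%). The level has 1 degree of freedom and the line within a level has 4, and the 9 other splits of the lines into 3 and 3 took between 7.15% and 9.79% in place of the level. Correlations between 2 samples of a line lay between 0.9926 and 0.9963, and those between samples of different lines between 0.9438 and 0.9746. BT474 and MdaMB361 were the most alike pair of lines, with a mean correlation of 0.974, and BT20 and T47D the least alike, with 0.9441.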

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

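The 3 single samples and the differences between Hypo lines given here came from rules applied to every tested group or pair, and no explanation was weighed in this part.

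In 3 of 320 groups of 9 samples a single sample stood apart from the other 8. The rule's chance rate of about 1 in 20 groups holds for independent values. Each group here holds 3 samples of each of 3 lines, so the count cannot be set against that rate. SNORD116-21 was at 4.28 in SkBr3 sample 1 and between 3.55 and 3.90 in the other Hypo samples. LUM, a matrix proteoglycan, was at 3.83 in MCF7 sample 1 and between 3.23 and 3.47 in the other Hypo samples. PLAC8 was at 3.98 in BT474 sample 2 and between 4.69 and 5.14 in the other Acetyl samples. All of these values lie near the low end of the scale.

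The Hypo lines differed from each other in their distance from the Acetyl lines for 6 pairs of lines and lists, by a test of the difference itself (camera with an estimated correlation). In 3 of them the medians also lay on opposite sides of the Acetyl lines. Basal epithelial genes had a median of 1.78 in BT20 and -0.13 in MCF7 against the Acetyl lines, with an adjusted p of 5.7e-04 for the difference. Genes of the ERBB2 amplicon had medians of -1.08 in BT20, -1.39 in MCF7 and 0.87 in SkBr3. The difference had an adjusted p of 0.00315 between BT20 and SkBr3 and 0.0021 between MCF7 and SkBr3. In the other 3 both medians lay on the same side. Basal epithelial genes had 1.78 in BT20 and 0.14 in SkBr3 (adjusted p 0.00176), oestrogen receptor and luminal genes -2.13 in BT20 and -0.20 in MCF7 (adjusted p 0.00638), and apocrine genes -1.98 in BT20 and -0.51 in SkBr3 (adjusted p 0.0379).

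Probe sets that name no single gene were left out of the gene tests, and 145 of them separated the levels in all 9 line pairs, 54 higher and 91 lower in the Acetyl lines. These counts come from 1 fit, with 1 adjustment, of 12083 probe sets with no symbol and 1754 with several. Fitted and adjusted as 2 separate groups, 16 higher and 52 lower separated the levels among those with no symbol and 38 and 33 among those with several. The study has no control samples for this signal, and what these probe sets measure was not tested.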

How the results depend on the processing

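Every alternative given here was fixed with the tests, and none was chosen after the results were seen. The cause was not tested where a value changed, except where fewer lines or another error term is the change itself.

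For Acetyl against Hypo on line means (0 higher, 0 lower), intensity trend with robust moderation called 3 higher genes and an adjusted p of 0.1 called 6. With 18 samples and the line as a random block 378 were higher and 303 lower, as if independent 1653 and 1622, and with line coefficients and the error within lines 5323 and 5328. Leaving out a line gave 0 to 9 higher and 0 to 4 lower, with 2 and 4 without MCF7, 7 and 3 without SkBr3 and 9 and 3 without T47D. Leaving out a sample gave 0 and 0.

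The replicate number as a block beside the random line block gave 280 higher and 225 lower genes. The numbers showed little pairing of samples. Residuals of 45 same-number pairs of different lines correlated between -0.297 and 0.33 (mean 0.014), and 8 passed 0.1. Pairs with different numbers had a mean of -0.007. Of the 18 samples 10 correlated best with a sample of their own number, so a weak pairing is not excluded. The replicate block left the counts for separating genes, lines and MCF7 within 1.5 times.

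With each of the 9 differences at least 1, 46 higher and 16 lower genes separated the levels. With no minimum difference the counts higher and lower were 5222 and 6241 in BT20, 4531 and 4749 in BT474, 5035 and 4679 in MCF7, 4759 and 4976 in MdaMB361, 4870 and 5368 in SkBr3, 4875 and 5087 in T47D, and 4971 and 4708 for MCF7 against the Acetyl lines. With every probe set tested, MdaMB361 had 722 lower and MCF7 against the Acetyl lines 1127 higher. With the spread between the Acetyl lines as the error, MCF7 had 0 higher and 0 lower genes in limma, against 796 and 584 at an unadjusted p under 0.05.

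With an estimated correlation 0 lists were higher and 0 lower between the levels, and 12 of 38 pairs of list and line passed. With a random line block 4 lists were lower. Leaving out a line gave 2 to 5 higher and 0 to 5 lower lists: 2 and 0 without BT474, and lower lists numbered 1 without BT20, 4 without MCF7 and 5 without SkBr3. List directions changed for cell cycle (adjusted p 0.0632, range 0.00721 to 0.869), sterol synthesis (0.604, range 0.00376 to 0.604) and fibroblast markers (0.511, range 0.411 to 0.936) without BT20. They changed for histone genes without BT474 (0.501), MCF7 (0.0444) and T47D (0.567), range 0.0270 to 0.576, and for acetyl-lysine readers without SkBr3 (0.985, range 0.467 to 0.985). Without the 40% lowest genes they changed for cancer-testis genes (0.873).

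Of 690 level differences with a line left out 9 changed sign, none of them called. CLDN3 was -0.17 without BT20 (to 1.57), SAGE1 0.0130 without BT20 (from -1.10), and S100A4 -0.03 without BT20 and -0.0946 without MCF7 (to 1.65). CLDN1 was 0.01 without BT474 (from -3.43) and VIM -0.13 without BT474 (to 1.73). CD14 was 0.12 without MCF7 (from -0.37), PIP -0.0025 without T47D (to 3.70) and STARD4 -0.0150 without T47D (to 1.02). The other 681 kept their sign, 10 of them now called.

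Median variance shares without the 40% lowest genes were 13.3% for the level, 75.6% for the line and 3.86% for the samples, and the level had 10.4% after quantile normalization. Under quantile normalization, centring, the mean of clusters, every probe set, and trend with robust moderation, the 115 level, 48 line and 16 MCF7 genes named kept direction and call, as did all with a sample left out. Of the 115 level genes 60 gained a call with the line as a random block, 54 with the replicate block added, 78 as if independent and 114 with line coefficients, and all 16 MCF7 genes lost theirs on line means. Without the 40% lowest genes the 95 level, 29 line and 12 MCF7 genes left kept theirs. Signal over background is unknown, so whether the lowest values are signal was not decided.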

Other observations

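The tests of SNORD116, of the oestrogen receptor list, of neighbouring genes, of the splits for lists between levels and of BT20 with SkBr3, and the gene families and chromosomes, were chosen after the results were seen. The splits and regroupings for gene counts and for lists in each line, and the first test of receptor status, were not.

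The 6 lines make 10 splits into 3 and 3, which are too few for a share under 0.05. No gene was called by limma in the split by level, in 10 of 10 splits the count was as large, and the highest of the others was also 0. At an unadjusted p under 0.05 the split by level gave 1294 genes and the others 509 to 1035. For separating genes the split by level was the only 1 of 10 with as many, with 681 against at most 555. For gene lists 3 of 10 splits passed as many as the 6 of the split by level, with a highest other of 8. Line means of 2304 genes, or 12.53%, did not overlap between the levels, where chance gives 10%, and the highest other split had 2197.

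For single lines, 100 regroupings of the samples excluded a chance assignment of samples to lines and nothing more. A regrouping parts the samples of a line, so the differences between lines enter the error, and most regroupings called 0 genes. The counts therefore show that samples group by line, and do not show that the differences would hold in other cultures. The real count was reached in 1 regrouping, itself, for BT20 (2144, highest other 660), BT474 (1336, highest other 15), MCF7 (1358, highest other 57), SkBr3 (1703, highest other 1152), T47D (1485, highest other 11) and MCF7 against the Acetyl lines (1521, highest other 1324). For MdaMB361 it was reached in 2 (1197, highest other 1616). For lists in each line the 38 pairs were reached in 2, but the other regroupings passed 14 to 38 with a median of 25, so most of the count at the preset correlation also arises in mixed groups.

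SNORD116 copies were higher in all 3 Acetyl lines, with a median difference of 2.70 over 20 copies and 18 that separated the levels. The tables argue against a differing yield of small RNAs, and against copy number only in part. A yield of small RNAs that differed between lines would raise the other 172 small nucleolar RNAs too, and their median difference was -0.27, with 0 at or above the median of the copies. Scaling of the arrays left the median at 2.70 after centring and 2.72 after quantile normalization. The medians of the deposited arrays lay between 6.73 and 6.81, so these steps could hardly have moved it. They show only that no whole-array shift of that size remained, and cannot decide on the normalization before deposition. A copy number change of the whole region as large as the copies' difference would move the neighbours. The 15 neighbours above the lowest 40% of genes, UBE3A among them, had a median of -0.11 and a highest of 0.61. They cannot decide on loss of the expressed allele, which in an imprinted cluster could silence the copies and move the neighbours little. Cross-hybridisation between the related copies stays open for the share of each copy, and a difference in the imprinted state or transcription of the locus may underlie the pattern. That hypothesis came from the same 6 lines, and neither it nor a relation to acetylation was tested.

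The higher oestrogen receptor and luminal list is confounded in part with receptor status, since the Acetyl lines all have high ESR1 and BT20 and SkBr3 have low ESR1. The members were higher in the Acetyl lines by a median of 2.13 against BT20, 1.04 against SkBr3 and 0.20 against MCF7, and 27, 24 and 16 of 29 were higher. The median for MCF7 was 0.113 of that for BT20 and SkBr3, so the list's difference lay mainly against the lines with low ESR1. The list is made of receptor and luminal genes, ESR1 and GREB1 among them. The ratio is therefore no independent test of receptor status as the source. For the named level genes the median ratio of the MCF7 difference to the level difference was 1.01. That is a void test, since those genes were picked because they separate MCF7 from the Acetyl lines as well. PGR differed by -3.53 between MCF7 and the Acetyl lines at a like level of ESR1, which receptor status alone leaves open.

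Grouping BT20 with SkBr3 against the other 4 lines called 16 genes in limma on line means, and 1 of 15 splits into 2 and 4 had as many, with a highest other of 5. These splits are too few for a share under 0.05. OLFM4 was -7.07, VGLL1 -6.10, WNT5A -4.83 and CD274, which encodes PD-L1, -2.78 in the 4 lines relative to BT20 and SkBr3, and GREB1 was 5.64 and IGFBP4 3.83.

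Separating genes lay beside each other on chromosomes more often than in shuffled gene order, with 42 neighbouring pairs of the same direction against a mean of 11.0 and an upper bound of 18 in the shuffles. In all 9 other splits of the lines the count, between 11 and 52, also passed its shuffles. The split by level had the lowest ratio of the count to the shuffled mean, at 3.81, and the other splits had 4.43 to 11.9. Copy number differences between the lines may account for part of the separating genes, as amplification and loss in established lines would. Shuffled gene order does not tell these from neighbours that are regulated together, so the cause was not decided. Neighbours are thus not independent, so no p-value is given for single chromosomes, and the other splits were not counted by chromosome. On chromosome X, 31 genes were lower against 12.1 expected from an even spread and 25 higher against 13.7. The 2 directions lay in different parts of the chromosome. In consecutive stretches of neighbouring genes, the first 6 stretches (300 genes) held 24 higher and 0 lower genes. Stretches 10 to 12 (150 genes) held 27 lower and 0 higher. These parts were picked from the counts, so they describe the pattern and test nothing. Chromosome 1 had 56 lower against 32.4 and 21 higher against 36.8. Higher genes numbered 36 against 19.4 on chromosome 12, 35 against 21.0 on 17 and 12 against 5.2 on 18. They numbered 25 against 11.4 on 15, but 18 of these are SNORD116 copies, a single locus, and the others show no excess. They numbered 10 against 22.8 on chromosome 2 and 1 against 10.5 on 20.

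Metallothioneins, which bind zinc and copper, were below 0 in the Acetyl lines for 11 of 11 measured genes, with a median of -1.06, and 9 separated the levels. They share sequence, so single members are uncertain. Of 23 immediate early genes 21 were below 0, with a median of -0.86, and 8 separated the levels, among them FOS, FOSB, EGR1, DUSP1 at -2.14, ATF3 at -1.26 and IER2 at -0.86. After quantile normalization 20 of 23 were below 0. Of 18 clustered protocadherin beta genes 0 were below 0, with a median of 1.26, and 5 separated the levels. For some of the others the difference came mainly from T47D. PCDHB8, PCDHB5 and PCDHB13 were at 9.97, 10.02 and 10.17 in T47D and at or below 5.15, 6.225 and 6.87 in every other line. Under both scalings the medians of these families kept their sign. No explanation was tested for these families, and adjusted p on line means did not pass for any member.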
